A study of Mus musculus with 2 samples.

How the data were processed

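H3K9me3 ChIP-seq was done on 2 pools of newborn mouse hearts. Per the labels, library fragments were 300 to 500 bp, each biological replicate combined 2 technical replicates, and coordinates are mm10. Per the deposited text notes on the files, each replicate's peak list was made from its own alignment and its own control file, the pooled list from both alignments and both controls, and the replicated list from these 3 lists. The rule behind the replicated list is not stated, so it was examined on the files. The aligner, peak caller, versions and duplicate or mapping filters are not given in the sources used here. How reads in repeats and near-identical genes were placed is therefore unknown.

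The deposited peak lists give per peak a ratio, taken as the fold enrichment over the control at the summit by the authors' caller. They also give −log10 p and −log10 q values by the authors' caller. A display score and a summit offset are among the deposited columns and entered no result. Fold enrichment is each peak's own value within its list and was used only to rank, filter or describe peaks. Replicate lists include weak peaks (the lowest −log10 p was 2.02 in replicate 1 and 2.10 in replicate 2), so their lengths depend on a permissive threshold. With no counts, depth per sample is unknown, and no interval that needs it is given. All columns used belong to a mapped sample or to the authors' pooled lists.

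Genes were the 21938 protein-coding genes of GENCODE M21 on chromosomes 1 to 19, X and Y, and sequence came from the soft-masked GRCm38 assembly. Peaks on scaffolds entered only the counts of peaks and their covered lengths. Promoters were 1 kb either side of a transcription start site, and each base was counted once as promoter, coding exon, UTR, intron or intergenic, in that order. A gene was said to carry H3K9me3 if a replicated peak overlapped its body by at least 1 base. The first and last exons were those of the longest protein-coding transcript.

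Replicate overlap and feature shares were compared with 1000 circular shifts of peaks within each chromosome between its first and last peak, and sequence shares with 100. The 16 gene lists were compared with 10000 random lists matched in 20 bins of gene length. Exon ends were compared by a sign-flip permutation test over genes with 100000 resamples. Tests were two-sided with a threshold of 0.05, and Benjamini-Hochberg adjustment ran over the features or the lists. The smallest p-values possible were 0.002, 0.0198, 0.0002 and 1e-05. List tests treat genes as independent draws, and members of tandem families are neighbours, so rotation along gene order was run as an alternative. Genes and peaks are not biological replicates, so these p-values describe placement in these 2 pools. With n = 2, an SD between replicates rests on a single difference.

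The tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Named were the 10 replicated peaks of highest fold, the 10 densest 1 Mb windows, the 10 genes with most covered bases, the 10 of at least 5 kb with the highest covered share, and up to 4 genes per list with the most covered bases. Single genes cited within windows were chosen after their values were seen. Alternatives changed the threshold (−log10 q of at least 2, or fold at or above the list's median), the overlap required, merging of peaks at most 1 kb apart, window length, promoter size, the null, the chromosomes, the replicate used and the peak list. Added after seeing the data were a set of replicated peaks met in both replicate lists, a rotation adjusted for gene length, the overlap and rank correlation without X and Y, and a count of windows rich in any of 5 tandem lists, chosen once the count of Zfp-rich windows had been seen to move between settings.

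The tests were tested on simulated data first: 0.5% of random 40-gene lists were called, lists with tripled odds were called 52% of the time at 40 genes and 100% at 200 genes, and 3 of 20 shifted peak sets gave a false feature call. The simulated lists were drawn from all genes without regard to position, so their rates do not cover lists of neighbouring genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.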

Results

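H3K9me3, the trimethylation of lysine 9 on histone H3, marks constitutive heterochromatin and silenced gene families. It was mapped by ChIP-seq in hearts of newborn mice (postnatal day 0, males and females pooled, healthy animals of C57BL/6N substrains). There was 1 group with 2 biological replicates, each a separate pool of hearts. Replicate 1 came from 15 mice, and the pool size of replicate 2 is not stated. Each replicate joined 2 technical replicates. The labels name no second tissue, age or treatment, so the data describe where the mark lies in the newborn heart and how far the pools agree. Coordinates are mm10 (GRCm38), counted from 1. The peak lists hold no read counts, so the depth of each sample is unknown. Scaffolds included, replicate 1 had 54179 peaks over 15.0 Mb and replicate 2 had 44072 peaks over 13.6 Mb. On chromosomes 1 to 19, X and Y their peaks covered 0.562% and 0.507% of the sequenced bases. The authors' pooled list held 83599 peaks. Their replicated list, used for the main values below, held 20385 peaks over 10.4 Mb with scaffolds, and 0.386% of the sequenced bases of these chromosomes, with a median length of 428 bp and a median fold enrichment of 3.41.

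The pools shared most of their densest H3K9me3 windows but few single peaks. Of the 50 densest 1 Mb windows of each replicate, 46 were common to both, where 0.913 would be common by chance. The protocadherin window on chromosome 18 and a window of vomeronasal receptor and Zfp genes on chromosome 7 ranked first and second in both. Peak by peak, 16.7% of replicate 1 peaks had at least 50% of their bases inside replicate 2 peaks, against 0.548% ± 0.0444 (SD over 1000 circular shifts), and 18.7% of replicate 2 peaks lay so in replicate 1 peaks, against 0.594% ± 0.0511. With 90% of the bases required the shares were 6.51% and 5.75%. Both two-sided permutation p-values were 0.002, the smallest that the shifts can give. Over 13743 overlapping pairs of peaks the authors' fold enrichments had a Spearman rho of 0.159, a description across peaks, which are not independent replicates. Only 13.1% of replicate 1 peaks and 19.4% of replicate 2 peaks had a −log10 q of at least 2, against 85.5% of replicated peaks. All 20385 replicated peaks were identical to a pooled peak. Of these, 11900 (58.4%) met peaks of both replicates by at least 50% of either peak, and 8485 did not, with 559 touching neither replicate's list.

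Zfp genes, which encode zinc finger proteins often organised in tandem clusters, carried H3K9me3 more often than other genes of their length. A replicated peak overlapped 152 of 391 Zfp genes (38.9%), where random lists matched on gene length gave 41.7 (95% range 31 to 53), a ratio of 3.64 (two-sided permutation p = 0.0002, adjusted p = 0.0008). With each replicate's own peaks the share was 44.5% ± 1.09 (SD, n = 2). Zfp981 on chromosome 4 (146502027 to 146539395) had the most covered bases of the list, 13549 bp in 20 peaks. Zfp110 on chromosome 7 (12834761 to 12850577) was covered over 78.6% of its gene body and Zfp873 on chromosome 10 (82048123 to 82064745) over 70.3%. Zfp943 on chromosome 17 held 9619 covered bp. Zfp68 (57.1%) and Zfp606 (45.9%) were also among the 10 genes of at least 5 kb with the highest covered share. The list was called higher under every alternative run except 1 kb either side of the transcription start site, where the ratio was 1.68 with an adjusted p of 0.555. The ratio was 2.38 with replicate 1 alone and 2.2 in the pooled list (adjusted permutation p = 0.00064 and 0.000533).

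In Zfp genes the mark covered the last exon, which usually encodes the array of zinc fingers, far more than the first exon. The gene body between them was not compared, and it also carried the mark. Of the 4 genes of the list named for covered bases, the strongest peak was intronic in Zfp981, Zfp110 and Zfp873 and in a coding exon in Zfp943. In 150 Zfp genes with at least 3 exons and a replicated peak, the last exon had 1275 bp covered on average and the first exon 0.68 bp, a difference of 1274 bp ± 94.7 (SE over genes; sign-flip permutation test over genes, two-sided p = 1e-05, the smallest that 100000 resamples can give). The last exon was touched by a peak in 111 of these genes and the first exon in 1. Last exons were longer, with a median of 2697 bp against 145 bp. As a share of exon bases, 43.5% of the last exon was covered and 0.667% of the first (p = 1e-05, permutation). In 2559 other multi-exon genes with a peak, 49.6 bp of the last exon and 16.4 bp of the first were covered (p = 1e-05, permutation), and as shares 2.51% and 2.44%, which did not differ (p = 0.821, permutation). A coding-exon peak of Zfp329 on chromosome 7 (12809156 to 12811676) had a fold enrichment of 8.61 and one of Zfp958 on chromosome 8 (4628137 to 4630505) had 8.07, both among the 10 highest of the replicated list.

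**Figure D1:**
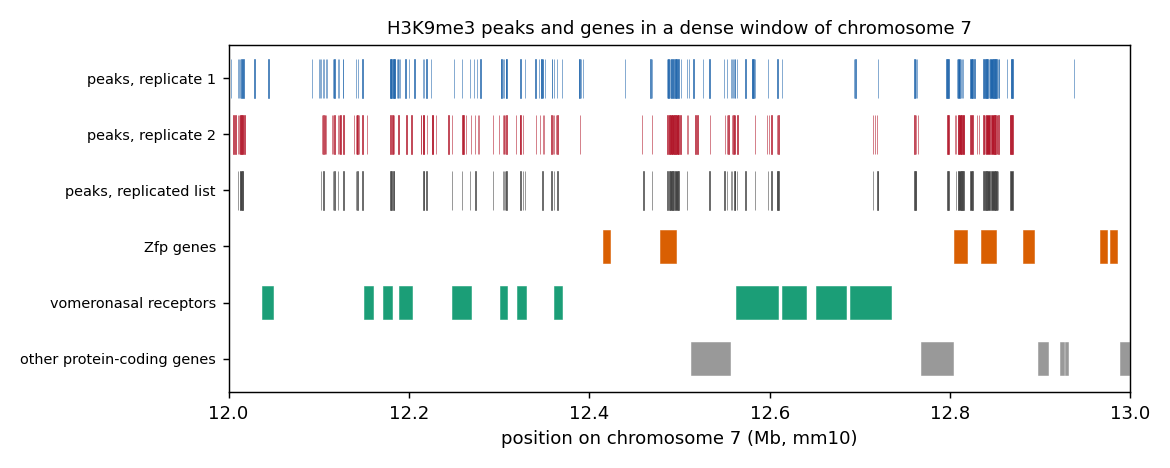
Peaks of replicate 1, replicate 2 and the replicated list (vertical bars, upper 3 rows) and protein-coding genes by group (boxes, lower 3 rows) between 12 and 13 Mb of chromosome 7, mm10; the x axis is the position in Mb. The window held 95 replicated peaks over 68955 bp, densest around Zfp606, Zfp329 and Zfp110.

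The clustered protocadherins, neuronal adhesion proteins encoded in tandem on chromosome 18, lay in the densest 1 Mb window. Replicated peaks covered 82511 bp of the window from 37000001 to 38000000 (68240 bp in replicate 1, 79078 bp in replicate 2) and overlapped 44 of 57 protocadherin genes, against 15.2 in length-matched lists (ratio 2.90, adjusted p = 0.0008, permutation). The ratio was 1.90 in the pooled list, 5.95 under rotation along gene order and 34.0 around start sites, where 28 of 57 genes had a peak against 0.823 expected. Pcdhga1 (37661793 to 37841873) had 37246 covered bp in 52 peaks, Pcdhga2 35461 bp, Pcdhga3 34172 bp and Pcdhgb1 32970 bp. These gene bodies overlap and share most of these peaks, so their values are not independent. The same holds for Gm42416, Gm37013 and Gm37388, annotated models that span the cluster and had the most covered bases of all genes (86512, 83817 and 83814 bp). Outside the cluster only Tmem132d, a transmembrane protein gene on chromosome 5 (127781630 to 128433077), was among the 10 genes with the most covered bases, with 57742 bp in 116 peaks.

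Vomeronasal and olfactory receptors, the large chemoreceptor families, and other tandem families also overlapped peaks more often than random lists. Peaks met 64 of 327 vomeronasal receptors (ratio 3.09, adjusted p = 0.0008, permutation), led by Vmn2r60 on chromosome 7 with 5801 covered bp in 14 peaks and Vmn2r102 on chromosome 17 with 3677 bp. They met 79 of 1093 olfactory receptors (ratio 2.18, adjusted p = 0.0008, permutation), with 3174 bp in Olfr139 and 2214 bp in Olfr1349. Of the other tandem families, 34 of 280 genes had a peak (ratio 1.90, adjusted p = 0.00128, permutation), led by Skint5 (16299 bp) and Skint6 (15627 bp) on chromosome 4, genes of T cell selection in skin. Ugt1a7c and Ugt1a10, glucuronosyltransferase genes on chromosome 1, had 9152 and 8154 covered bp. Ugt1a1 in the same locus was covered over 90.5% of its body, the highest share of any gene of at least 5 kb. The bodies of Ugt1a7c and Ugt1a10 contain that of Ugt1a1, so these values share bases. Such overlapping genes count separately among the 34. The strongest peak of Ugt1a1 had a fold of 3.46 with a −log10 q of 19.8. At a similar fold of 3.49, that of Kcnq1 had 3.54. Without read counts, a raised control at the Ugt1a locus could not be looked for. Rotating list positions along gene order, a permutation that ignores gene length, took the olfactory ratio to 0.546 (adjusted p = 0.00799) and that of other tandem families to 0.925 (adjusted p = 0.887) and ended the vomeronasal call (ratio 1.49, adjusted p = 0.149), while a length-adjusted rotation permutation, added after seeing the data, kept the vomeronasal call (adjusted p = 0.0107) but neither of the others (ratios 2.18 and 1.95, adjusted p = 0.110 and 0.107). By permutation the olfactory call was also lost when 500 covered bases were required (ratio 1.26, adjusted p = 0.607) and with only peaks met in both replicates (ratio 1.36, adjusted p = 0.210), and that of other tandem families around start sites (ratio 1.85, adjusted p = 0.386).

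Tandem families lay in several of the other dense windows. The second densest, on chromosome 7 from 12000001 to 13000000, held 7 Zfp genes and 12 vomeronasal receptors. Of its 25 protein-coding genes, 12 overlapped a replicated peak. Among the Zfp genes, Zfp606, Zfp329 and Zfp110 did, and Zfp551, Zfp128, Zfp324 and Zfp446 did not. On chromosome 10 from 82000001 to 83000000, 65741 bp were covered around Zfp873, Zfp938 and AU041133. The window on chromosome 12 from 114000001 to 115000000 held no protein-coding gene but 49 immunoglobulin heavy-chain V genes, of which 12 overlapped a peak. Windows followed with pregnancy-specific glycoprotein and Ceacam genes such as Psg16 and Ceacam5 (chromosome 7, 17000001 to 18000000), 6 Skint genes (chromosome 4, 112000001 to 113000000), the Ugt1a locus (chromosome 1, 88000001 to 89000000), 7 Zfp genes (chromosome 17, 22000001 to 23000000), Ncor2 and Tmem132b (chromosome 5, 125000001 to 126000000) and vomeronasal receptors with Nlrp4b (chromosome 7, 10000001 to 11000000). In the Ugt1a window, 24411 of the 59677 covered bp lay in Mroh2a (88226986 to 88262289), 69.1% of its body. This gene lies outside the bodies of Ugt1a1, Ugt1a7c and Ugt1a10. Its strongest peak had a fold of 3.32 with a −log10 q of 14.7, and a raised control could not be looked for there either. The 10 windows held 6.10% of all covered bases. At least 5 Zfp genes lay in 2 of the 10, against 20 of all 2737 windows. This count moved from 0 with 500 kb windows to 4 with the stronger peaks by fold.

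**Figure D2:**
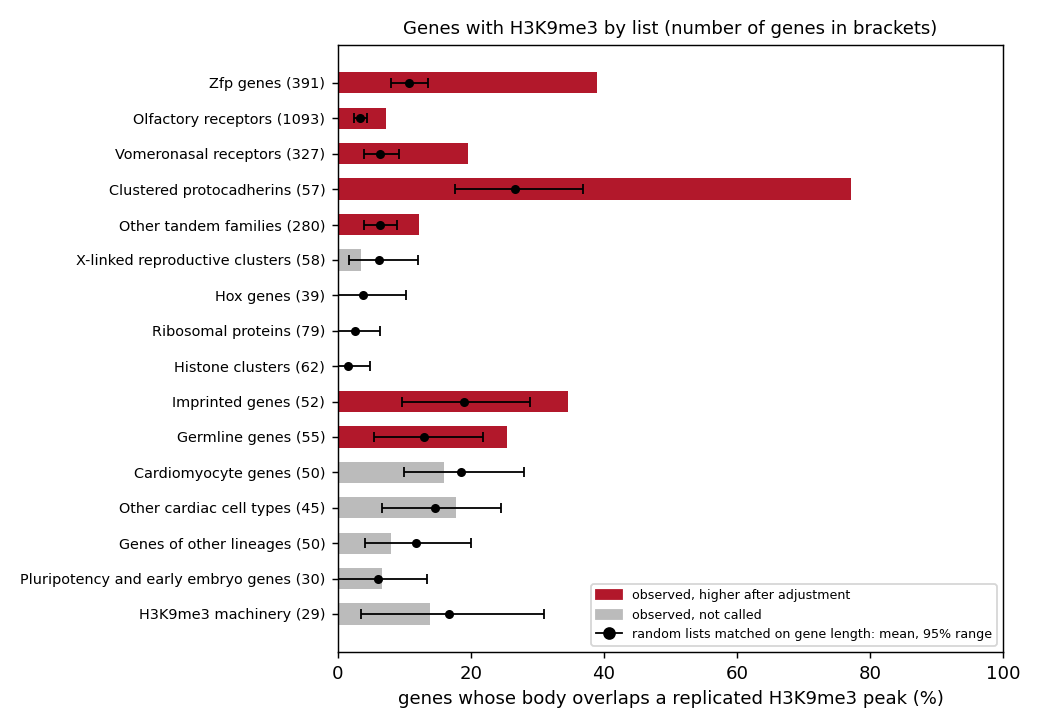
Percent of the genes of each list whose body overlaps a replicated peak (bars; red, higher than length-matched random lists after adjustment; grey, not called) with the mean and 95% range of 10000 random lists (black points and lines). Protocadherins reached 77.2% and Zfp genes 38.9%, while no Hox, ribosomal protein or histone gene had a peak.

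Imprinted and germline genes carried H3K9me3 more often than length-matched genes. Peaks overlapped 18 of 52 imprinted genes (ratio 1.83, adjusted p = 0.0139, permutation). Gnas on chromosome 2 had 5999 covered bp in 6 peaks, with its strongest peak at a promoter (174296967 to 174297258, fold 4.39). Mest on chromosome 6 had 2532 bp with its strongest peak at a promoter (30738073 to 30738845, fold 4.53), Kcnq1 4084 bp and Commd1 1666 bp, both with their strongest peak in an intron. Peaks overlapped 14 of 55 germline genes (ratio 1.98, adjusted p = 0.0261, permutation). Nlrp5, an oocyte gene on chromosome 7, had 8631 covered bp in 13 peaks. Promoter peaks lay at D1Pas1 (chromosome 1, 186966611 to 186968865, fold 5.02) and Taf7l (X, 134475152 to 134476551, fold 4.66), genes of the testis, and Tdrd9 of the piRNA pathway had 2092 bp. Around start sites 5 imprinted genes had a peak against 0.615 expected (ratio 8.13, adjusted permutation p = 0.00192), and 11 germline genes against 0.602 (ratio 18.3, adjusted p = 0.0008). The imprinted call was lost with only the stronger peaks by fold (ratio 1.78, adjusted permutation p = 0.0992), and the germline call with only peaks met in both replicates (ratio 1.75, adjusted p = 0.257) and under rotation without length adjustment (ratio 1.93, adjusted p = 0.0639).

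Genes of the heart itself did not stand apart. Peaks overlapped 8 of 50 cardiomyocyte genes (ratio 0.863, adjusted permutation p = 0.854). Kcnq1 had the most covered bases of this list, 4084 bp in 3 peaks, and counts in the imprinted list as well. The strongest peak of each named gene of the cardiomyocyte list was intronic. Scn5a, the cardiac sodium channel, had 1607 covered bp of a 95609 bp gene, the calcium channel Cacna1c 990 bp of 609179 bp, and the creatine kinase Ckmt2 1087 bp. Among genes of other cardiac cell types 8 of 45 had a peak (ratio 1.22, adjusted permutation p = 0.854), including Ddr2 (1877 bp), Adgre1 (1264 bp), Pdgfrb (1148 bp) and Tek (758 bp). Genes of other lineages met peaks in 4 of 50 (Syt1, Trp63, Snap25 and Hnf1a; adjusted permutation p = 0.771), pluripotency and early embryo genes in 2 of 30 (Zfp42 and Esrrb; adjusted p = 1), genes of the H3K9me3 machinery in 4 of 29 (Atf7ip, Hells, Kdm4a and Pphln1; adjusted p = 0.969) and X-linked reproductive clusters in 2 of 58 (Rhox13 and Mageb18; adjusted p = 0.771). Of these genes, Hnf1a, Kdm4a and Pphln1 had no covered base in replicate 2's own list. The peaks of Kdm4a (−log10 q 1.08), Pphln1 (1.01), and Trp63, Esrrb and Mageb18 (1.79 each) were weak. With replicate 1 alone the ratio for other lineages was 1.47 (15 of 50) against 0.685 in the replicated list and 0.672 (6 of 50) with replicate 2 alone, not called in any (adjusted permutation p = 0.128, 0.771 and 0.432). None of 39 Hox genes, 79 ribosomal protein genes or 62 histone genes had a replicated peak, with 1.48, 2.01 and 0.962 expected (adjusted permutation p = 0.754, 0.515 and 0.854). The 95% ranges of the random lists start at 0 for all 3, so a count of 0 could not be called lower. Hox genes had peaks in the other lists, 2 of 39 with replicate 1 alone (ratio 0.635), 3 with replicate 2 alone (ratio 1.11) and 5 in the pooled list (ratio 1.23), none of them called. Ribosomal protein genes were called lower with replicate 1 alone (adjusted permutation p = 0.0368), and under the rotation permutation without length adjustment ribosomal protein genes (adjusted p = 0.00799) and histone genes (adjusted p = 0.048) were. All other p-values here are from permutation of length-matched lists, 16 in all. Lists of about 50 genes have limited power, since simulated lists of 40 genes drawn with tripled odds were called 52% of the time.

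Chromosomes 7 and 17 carried the most H3K9me3 per base. Relative to the autosomes together, chromosome 7 had 1.94 times the covered bases per Mb in the replicated list and 1.74 ± 0.0224 in the replicates (SD, n = 2), and chromosome 17 had 1.71 and 1.61 ± 0.0761. They also hold the most Zfp genes of any chromosome, 92 and 45. Density did not follow Zfp number further down. Chromosomes 13, 4 and 2, next with 36, 30 and 28 Zfp genes, were at 1.01, 1.16 and 0.767 in the replicated list. Chromosome 5 followed at 1.39, and chromosome 14 was the lowest autosome at 0.606. X had 0.184 in the replicated list, but the pools differed: 0.791 in replicate 1 with 3085 X peaks, and 0.143 in replicate 2 with 450, a ratio of 5.55 where the autosomes ranged from 0.935 to 1.10. Y had 0.00999, with 5 replicated peaks, and 0.00768 in replicate 1 with 10 peaks and 0.0170 in replicate 2 with 25, a ratio of 0.453. No test was made between chromosomes.

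**Figure D3:**
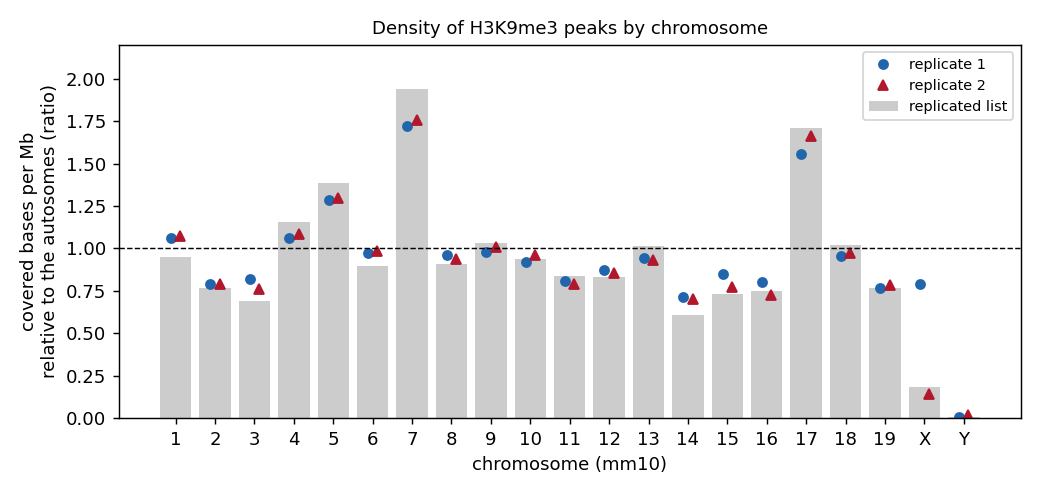
Covered bases per Mb of each chromosome divided by that of the autosomes together (y axis, ratio; dashed line at 1) for the replicated list (grey bars), replicate 1 (blue circles) and replicate 2 (red triangles). Chromosomes 7 and 17 stand highest in both replicates, and the replicates part on X, at 0.791 and 0.143, and on Y, where few peaks were called.

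By annotation, replicated peaks were enriched in coding exons and intergenic DNA and depleted from introns and promoters. Zfp last exons, with 1275 bp covered on average in 150 genes, count among these exon bases. Shares without Zfp genes were not computed, so an exon excess outside Zfp genes is not shown. Coding exons held 2.57% of peak bases against 1.21% expected from 1000 circular shifts (95% range 1.07% to 1.38%), a ratio of 2.12 that was 1.34 by peak midpoints and 1.25 in the pooled list. Intergenic DNA held 66.8% against 58.0% (ratio 1.15), introns 26.8% against 36.8% (ratio 0.727), promoters 2.12% against 2.67% (ratio 0.794) and UTRs 1.73% against 1.32% (ratio 1.31). Each two-sided adjusted permutation p was 0.002, the smallest possible. In the replicates' own lists coding exons held 1.81% ± 0.202 and introns 25.3% ± 0.721 (SD, n = 2). The UTR excess turned to 0.922 by peak midpoints (adjusted permutation p = 0.322) and to 0.968 with replicate 1 alone (adjusted p = 0.573), and the promoter deficit missed the threshold with only peaks met in both replicates (ratio 0.852, adjusted p = 0.0799).

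Of the 10 replicated peaks with the highest fold enrichment, 4 lay outside protein-coding genes. The highest fold enrichment, 13.3, was at the promoter of Tcfl5 (chromosome 2, 180642652 to 180644217), a transcription factor of the testis. Next were a peak in an intron of Sfi1 (chromosome 11, 3166972 to 3167344, fold 10.5) and a peak in the UTR of Klf14, an imprinted intronless gene (chromosome 6, 30956321 to 30958710, fold 10.3). A Y peak (259011 to 259480, fold 9.63) lay 465647 bp from the nearest gene, Zfy1. Its −log10 q of 63.6 was the highest of the 10, above the 54.9 of the Tcfl5 peak despite a lower fold. Without read counts, a raised control at this Y position could not be looked for. Of the remaining peaks among the top 10 beyond Zfp329 and Zfp958, 1 was in the UTR of 2610008E11Rik (chromosome 10, 79064064 to 79065752, fold 8.25) and 3 were intergenic, on chromosomes 1, 17 and 12, the first of them 2041 bp from Orc2. Asmt, the last enzyme of melatonin synthesis at the end of X, was covered over 75.5% of its body and Il3ra, an interleukin receptor gene, over 71.7%. Peaks had 43.8% GC against 42.0% ± 0.211 (SD over 100 shifts) and 27.4% soft-masked repeat bases against 33.7% ± 0.495 (two-sided permutation p = 0.0198 for both, the smallest possible). CpG was 0.801% against 0.854% ± 0.0189 (permutation p = 0.0198), a deficit not called for the stronger peaks by fold (ratio 0.971, p = 0.139) or for peaks met in both replicates (ratio 0.985, p = 0.515).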

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

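Peaks also lay on unplaced and unlocalized scaffolds, sequence that the comparisons by gene and chromosome do not use. The replicated list had 186 such peaks on 21 scaffolds, 1.64% of its covered bases, and 45 of them were on a single scaffold. Replicate 1 had 283 and replicate 2 had 242. Their median fold in the replicated list was 3.33 against 3.41 on the chromosomes, while their median −log10 p was 11.8 against 6.41. The difference between these medians was not tested, and no explanation was tested.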

How the results depend on the processing

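Over the settings run, 117 recomputed main values kept their direction and side of the threshold or, where no test was made, stayed within 1 SD between replicates (within 1.5 times for counts), while 23 moved, 3 turned and 3 lost their call. The fold correlation has no SD between replicates and was instead judged by an interval that treats pairs of peaks as independent. Of the values of single lists 166 stayed on their side of the threshold, 9 calls were lost, 3 appeared and 2 called ratios turned; ratios that were never called crossed 1 among the 166. Coding exon, intron and intergenic shares, both overlap shares, the Zfp last-exon excess, GC and soft-masked shares kept their call in every setting run, and the CpG deficit did not. The peak count was 10847 at or above the median fold, 83599 in the pooled list, 11900 for peaks met in both replicates, and 44072 to 54179 with single replicates. The fold correlation was 0.222 by −log10 p, 0.222 with 50% reciprocal overlap, 0.279 at −log10 q of at least 2 and 0.187 for the stronger peaks by fold. Chromosome 7's relative density was 1.98 for the stronger peaks by fold, 1.77 in the pooled list, 1.89 for peaks met in both replicates and 1.72 to 1.75 with single replicates, and that of X was 0.304 in the pooled list and 0.143 to 0.791 with single replicates, whose wide SD lets X move further than chromosome 7. Zfp-rich windows among the top 10 numbered 0 at 500 kb, 1 by peak number, 4 for the stronger peaks by fold and 1 to 2 with single replicates. By the added count, 6 of the 10 windows held at least 5 genes of the 5 tandem lists, and 3 at 500 kb; this count was chosen because the first moved, so its steadiness in the other settings is no independent evidence. The coding-exon ratio was 2.87 for the stronger peaks by fold and 1.42 with replicate 1 alone. The promoter ratio was 0.852 with peaks met in both replicates. The UTR ratio was 0.922 by midpoints, 0.928 in the pooled list and 0.968 to 1.08 with single replicates. Rotation without length adjustment left 3 lists higher and made 3 lower, turned the olfactory ratio to 0.546 and that of other tandem families to 0.925. These genes are short, and this null ignores length; the length-adjusted rotation gave ratios above 1 for both. Lists lower numbered 0 to 1 with single replicates. The Zfp ratio was 1.68 around start sites. With replicates 1 and 2 alone the ratio was 0.558 and 1.29 for pluripotency genes and 0.924 and 0.344 for X-linked clusters, on 2 to 6 genes with a peak and with no call. For the rest the cause was not tested. The alternatives named in the processing account as added, and only those, were chosen after seeing the data. Unknown depth limits what the absence of a peak means. No paired analysis was possible because there was 1 group.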

Other observations

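Beyond the fixed lists, 243 gene families defined by the letters that open their symbols, each with at least 10 genes, were tested against length-matched random lists, a scan chosen after seeing the data. None passed adjustment over the 243 families. At an unadjusted permutation p, the lowest were Ceacam, cell adhesion genes (6 of 15 genes with a peak, 0.884 expected, p = 0.0004), Nlrp, which includes oocyte genes (8 of 14, 2.26 expected, p = 0.0008), and Klra, natural killer cell receptors (5 of 11, 0.919 expected, p = 0.0012), each with an adjusted p of 0.0972. With 10000 lists the smallest p possible is 0.0002. In the immunoglobulin heavy-chain window on chromosome 12, 7 of 39 V pseudogenes overlapped a peak beside the 12 of 49 V genes.

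Of the tests below, that of looser calling was chosen after its result had been seen, and the bounds for even spread and for peak edges were tightened after their values were seen. No biological explanation was tested for these patterns, since the design has 1 group.

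X was covered more densely in replicate 1 than in replicate 2. In replicate 1, X (0.791) lay within the autosomes' range, from 0.716 on chromosome 14 to 1.72 on chromosome 7. In replicate 2, X (0.143) lay below the lowest autosome, chromosome 14 at 0.702. Y went the other way, with a ratio of 0.453 on 10 and 25 peaks. Both tests below look for an excess in replicate 1, so a deficit of X in replicate 2 was not tested. A looser threshold in replicate 1 would raise every chromosome alike, but X's ratio between replicates was 5.55 and the highest autosome's 1.10, which argues against it. Of the 3085 replicate 1 X peaks 3.99% touched a replicate 2 peak (median over autosomes 25.7%), but 25.1% of the 450 replicate 2 X peaks touched one of replicate 1 (autosomes 22.3% to 32.4%), so the first share largely follows the peak numbers, and 6.29% of replicate 1 X peaks had a −log10 q of at least 2, against a median of 13.7% over autosomes. A different X copy number in the chromatin and in its control could spread weak peaks evenly over X. The peaks that replicate 2 lacks had a variance over mean per 1 Mb of 11.2 on X (bootstrap 95% interval 7.05 to 16.6), within the autosomes' range of 5.07 to 29.4 and near their median of 11.0. A value at or above that median, as here, counted against this explanation under the bound as first written. The interval spans the median, so the test leaves the explanation open, and the sex make-up of each pool and control stays untested.

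H3K9me3 in the last exons of Zfp genes could arise from reads shared between near-identical gene copies. Of 185643 words of 31 bases within covered last-exon bases, 4.82% occurred more than once on the chromosomes (bootstrap 95% interval over genes 3.66 to 6.12), below the bound of 10% set before the count, which argues against exact copies as the main source. Over all last-exon words, covered or not, the share was 13.7%, while its median by gene was 4.07% in genes with covered words and 2.93% in the others. Genes with every last-exon word repeated (Zfp965, Zfp966, Zfp967, Zfp968, Zfp969, Zfp973 and Zfp989) had no covered word. Since read placement is unknown, a missing peak in such copies does not show absence of the mark. The share of Zfp genes with a peak is limited alike. In Zfp981, the Zfp gene with the most covered bases, 475 of 844 covered words were repeated, so shared reads stay open for single genes. Copies that differ by single bases were not counted, and how the authors placed such reads stays open.

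Peaks held fewer soft-masked bases than shifted peaks. A location in protein-coding genes does not account for it: outside their bodies the share was 27.9%, against 38.4% expected and at least 36.5% in each of the 100 shifts. Genes of other types, such as immunoglobulin V genes and pseudogenes, counted as outside, so a location in them was not tested. Another candidate explanation is that reads from repeats were not placed, so that peaks stop at repeats. The 500 bases on either side of peaks were 36.5% soft-masked, above the highest shift (34.7%), which met the bound as first written, but the share was higher at 2000 to 5000 bases (38.0%), so a repeat-rich neighbourhood would give the same excess and the explanation stays open.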
